A study of Mus musculus with 24 samples.

How the data were processed

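RNA from gastrocnemius, a mixed hind-limb muscle, was measured on 24 Illumina BeadChip arrays of male mice. Per the labels, total RNA was taken from powdered muscle with Trizol, treated with DNase and turned into biotin-labelled cRNA with a TotalPrep kit. Wild-type mice of the C57Bl/10ScSnJ strain made up 4 arrays, and mdx mice, which lack dystrophin, made up 4 groups of 5 arrays each. For 7 weeks those groups received PBS, PBS with voluntary wheel running, sActRIIB-Fc at 5 mg/kg once a week, or sActRIIB-Fc with running. sActRIIB-Fc is a soluble activin receptor type IIB fused to an antibody tail that captures myostatin, activins and related ligands. The labels name no injection for the wild-type mice, so genotype and PBS injection could not be separated.

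The deposited table of 25697 probes held intensity values, the mean bead signal of each probe, neither background-subtracted nor normalized. Beside each signal, per the file headers, stood the detection p-value of the probe against the negative control beads of its array, in steps that fit 798 controls. A separate deposited matrix held log2 values. These were the log2 of the quantile-normalized signal without background correction, with a largest difference of 0.0058 from that calculation on the same arrays. The software behind these files is not named in the sources used here. Every column belonged to 1 of the 5 groups, and no column was left unused.

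Work started from the intensity table. Background correction used normexp in limma 3.58.1 under R 4.3.3, with the control mean and spread inferred from the detection p-values and an offset of 16, followed by quantile normalization and the log2 transform. A probe was kept when its detection p was under 0.05 on at least 4 arrays, which left 12623 probes. Probe names came from the annotation supplied with the files. Of all probes, 23978 had 1 symbol, 1719 had none here, and 23962 symbols were matched to a reference gene identifier. Among the kept probes 11919 had a symbol. The probe with the highest mean stood for each gene, giving 8945 tested genes, of which 2216 had more than 1 tested probe. Where another probe of a named gene moved the other way, the text says so. A fold for a gene that was detected on no array of a group was computed against the level at the detection limit of those arrays and is written "at least".

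Genes were tested with limma, with 1 linear model over the 24 arrays holding a mean for each of the 5 groups, moderated by empirical Bayes, two-sided, and adjusted over the 8945 genes by Benjamini and Hochberg with a limit of 0.05. Contrasts compared PBS-injected mdx with wild type, each treatment with PBS-injected mdx, each treatment in the presence of the other, running and sActRIIB-Fc averaged over the other factor (10 arrays against 10), and the interaction of running with sActRIIB-Fc. Values are log2 fold changes ± standard error of the model, or group means ± SD.

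Gene lists were fixed before the data were examined, as were the comparisons, the tests and the first group of other settings below. There were 29 lists with 538 genes, of which 393 were tested. They covered the dystrophin complex, regeneration, extracellular matrix, macrophages, MHC class II, respiratory complex I, respiratory complexes II to V, the TCA cycle, fatty acid oxidation, mitochondrial biogenesis, glycolysis, slow and fast fibres, the activin and BMP pathway, atrophy, autophagy, the unfolded protein response, antioxidant genes, heat shock, immediate early genes, the cell cycle, the circadian clock, endothelium, adipocytes and the neuromuscular junction. These 25 lists had at least 5 tested members. The T and B cell, erythroid, neutrophil and Schwann cell lists had fewer and were not tested. Lists were compared with all other genes by camera in limma with a preset correlation of 0.01 between genes, adjusted over the 25 lists of each comparison. An estimated correlation and fry, a rotation test of whether the members move one way on balance, were run beside it with statmod 1.5.0. Between pairs of groups, the mean level of each list per array was also compared by an exact two-sided permutation test over arrays, unadjusted. It was not among the tests fixed in advance. The dystrophy score of an array was the mean level of the genes that rose in PBS-injected mdx minus that of the genes that fell, and was compared between groups that had no part in choosing those genes by exact two-sided permutation tests.

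Named genes followed a rule set before the data were examined. It took the 8 largest changes in each direction past adjusted p 0.05, up to 3 called members of lists that were called or held called members, a preset group of muscle genes, and, where almost nothing passed, the 8 genes with the lowest p. Genes chosen outside the rule, such as list members given as examples where no member passed, were picked after their values were seen.

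On simulated arrays with the real spread of each gene, changes of 0.5 log2 were recovered for 53.7% of genes in the mdx against wild-type contrast, 41.8% in running against PBS and 80.6% in the averaged running contrast. Changes of 1 log2 were recovered for 94, 92.5 and 97%, and changes of 2 log2 for 100%. No recovered gene had the wrong sign, and 7, 5 and 8 unchanged genes were called. A simulated shift of 0.3 in the fatty acid oxidation list was called at an adjusted p of 1e-28 with 0 other lists called. The simulated genes varied independently of each other. This run therefore does not show how often lists of genes that vary together are called without a shift.

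The other settings chosen in advance were no background correction, scaling to equal medians, the authors' log2 values, no detection filter, a stricter filter, all probes, trended robust variance, array weights, only the compared groups, the replicate number as a block, each array left out in turn, an estimated correlation and fry. A slide block was not run, because no slide is named. Added after seeing the data were 2 covariates, a hepatocyte index and the raw median signal of each array, and a run without the 4 arrays richest in hepatocyte transcripts. The index was the mean level of Apoa1, Apoa2, Ttr, Serpina1b, Ahsg, Ambp and Apoc3. For each comparison 100 splits of its arrays into groups of the same sizes, the real one included, were fitted again. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The number of arrays limits the precision of every value.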

Results

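Transcript levels were measured in the gastrocnemius of 24 male mice, on 1 array each. The age label of 6 to 7 weeks does not name the time point it belongs to. As an age at the end, it would place the start of 7 weeks of wheel running at or before birth. For the running mice it can therefore only be the age at the start, and the muscle was older when sampled. Wild-type mice gave 4 arrays. Dystrophin-deficient mdx mice gave 5 arrays in each of 4 groups. For 7 weeks these groups received PBS, PBS with voluntary wheel running, sActRIIB-Fc, or sActRIIB-Fc with running (the combination). Between 10404 and 11971 of the 25697 probes were detected per array, with 10404 to 10634 on the wild-type arrays and 10938 to 11971 on the mdx arrays. The raw median signal lay between 72.3 and 99.0. Correlations between arrays of a group ran from 0.965 to 0.990 in wild type, 0.986 to 0.993 under PBS, 0.977 to 0.992 under running, 0.988 to 0.993 under sActRIIB-Fc and 0.953 to 0.989 in the combination. Transcripts typical of hepatocytes differed widely between arrays of one group. Apoa1 ranged from 4.61 to 12.58 log2 units over the 24 arrays, and the mean of 7 such genes from 4.85 to 12.0 in wild type, 4.67 to 8.41 under PBS, 5.19 to 10.51 under running, 4.70 to 7.20 under sActRIIB-Fc and 4.67 to 10.65 in the combination.

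The first comparison asked how dystrophic muscle differed from healthy muscle. Of 8945 genes, 3376 (37.7%) differed between 5 PBS-injected mdx and 4 wild-type arrays, 1725 higher and 1651 lower. At least 2-fold changes numbered 511 upward and 139 downward. Myh8, the perinatal myosin heavy chain, rose 53.3-fold, from 6.86 ± 0.33 to 12.60 ± 0.53 log2 units (SD; log2 change 5.74 ± 0.32, adjusted p = 3.9e-12). Sln, which encodes the calcium pump inhibitor sarcolipin, rose 26.6-fold (4.73 ± 0.26, adjusted p = 3.6e-12), and Actc1, the cardiac actin of developing muscle, 15.4-fold (3.94 ± 0.17, adjusted p = 7.7e-14). The chemokine Ccl8 rose by 4.45 ± 0.44, the macrophage lectin Lgals3 by 4.36 ± 0.35, the protease inhibitor Timp1 by 4.16 ± 0.30 and Ms4a7 by 4.15 ± 0.40, each with an adjusted p of 3.9e-08 or less. Chrng, the fetal acetylcholine receptor subunit, was undetected in wild type and at least 11.6-fold higher in mdx. The strongest falls were in Dusp26 (-3.54 ± 0.18, adjusted p = 1.1e-12), Odf3l2 (-3.18 ± 0.29), the phosphatase regulator Ppp1r1a (-3.11 ± 0.14, adjusted p = 1.1e-13), Cntnap2 (-2.74 ± 0.19), Gnmt (-2.43 ± 0.88), Efcab6 (-2.29 ± 0.18), Ces1d (-2.20 ± 0.27) and the clock gene Ciart (-2.15 ± 0.39). Gnmt is a hepatocyte gene and ranged from 5.00 to 10.89 over the 24 arrays. Its call (adjusted p = 0.031) was lost without wild-type replicate 1 (0.051) or 2 (-1.47, 0.18) or PBS replicate 1 (0.062), 2 (0.053), 3 (0.062) or 5 (0.054).

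Genes of muscle regeneration, extracellular matrix, macrophages and antigen presentation rose together. In the regeneration list 11 of 12 tested members rose and none fell, with a median log2 change of 2.26 (camera adjusted p = 4.2e-11). Besides Myh8, Actc1 and Chrng, the fetal and embryonic proteins of new fibres, the remaining called members rose by smaller amounts. In the extracellular matrix list 19 of 20 members rose (median 1.54, adjusted p = 1.4e-15), among them the collagens Col3a1 (2.26 ± 0.27) and Col1a1 (2.10 ± 0.28) and the collagenase Mmp14 (2.25 ± 0.14). In the macrophage list 16 of 17 rose (median 2.96, adjusted p = 5.1e-16). Lgals3 was joined there by Gpnmb (3.75 ± 0.37) and by the lipid receptor Trem2, which was undetected in wild type and at least 9.43-fold higher. The 7 tested MHC class II genes all rose (median 2.31, adjusted p = 3e-10), including H2-Ab1 (2.80 ± 0.22), H2-Eb1 (2.71 ± 0.18) and the invariant chain Cd74 (2.66 ± 0.16). With an estimated correlation the regeneration, extracellular matrix and MHC class II calls held (adjusted p = 0.019, 0.019 and 0.048), and the macrophage call did not (adjusted p = 0.079 with an estimated correlation).

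A further 3 lists were called upward. In the cell cycle list 7 of 12 members rose and 1 fell, and 9 rose and 1 fell when adjusted over the list alone (median 0.98, adjusted p = 0.017). Cdc20 and Birc5, both active in mitosis, were undetected in wild type and at least 2.43-fold and 2.60-fold higher, the replication gene Mcm5 rose by 1.52 ± 0.36, and the mitotic kinase Aurka was the member that fell (-1.11 ± 0.16). In the immediate early list 6 of 12 rose and none fell (median 0.56, adjusted p = 0.013), led by Fos (2.11 ± 0.40), Egr1 (1.75 ± 0.23) and Junb (1.33 ± 0.21). In the unfolded protein response list 8 of 15 rose and 2 fell (median 0.40, adjusted p = 0.040), with the protein disulfide isomerases Pdia3 (0.91 ± 0.17) and Pdia4 (0.82 ± 0.15) and the transcription factor Xbp1 (0.67 ± 0.09) highest. These calls were lost (adjusted p = 0.49, 0.34 and 0.34 with an estimated correlation). The unfolded protein response call was also lost without wild-type replicate 4 (adjusted p = 0.053) or PBS replicate 2 (0.054), and with the hepatocyte index (mean 0.28, 0.052) or the raw median signal (0.26, 0.060) as a covariate, against a mean of 0.29. The cell cycle call was lost with the raw median signal as a covariate (mean 0.73 against 0.84, adjusted p = 0.051).

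Fatty acid oxidation genes fell. Of 22 tested members 17 fell and none rose (median -0.42, adjusted p = 3.9e-06; adjusted p = 0.068 with an estimated correlation). The largest falls were in Pdk4, the kinase that spares glucose by blocking pyruvate dehydrogenase (-2.08 ± 0.45), in Ucp3 (-1.75 ± 0.33) and in the dienoyl-CoA reductase Decr1 (-0.58 ± 0.14). In respiratory complex I, 7 of 32 members fell and none rose, and 3 fell when adjusted over the list alone (median -0.19, adjusted p = 0.012; adjusted p = 0.49 with an estimated correlation). Ndufb4 (-0.85 ± 0.24) and Ndufb11 (-0.56 ± 0.15) were among them. Complexes II to V were not called as a list (adjusted p = 0.38): Cox6a1 (0.60 ± 0.17) and Cox8a rose, the cytochrome c gene Cycs (-0.55 ± 0.10) was 1 of 2 that fell, and 34 of 38 did not pass. The TCA cycle list was not called either (adjusted p = 0.38), with 3 of 16 falling, Suclg2 (-0.59 ± 0.11) and Dld (-0.56 ± 0.17) among them, and 1 rising; adjusted over the list alone 2 fell. Of the regulators of mitochondrial biogenesis 5 of 12 fell and none rose (adjusted p = 0.059), with the nuclear receptor Esrrb (-1.47 ± 0.15) first, while the coactivator Ppargc1a was at -0.15 ± 0.15 (adjusted p = 0.47). In glycolysis 1 of 16 members fell (adjusted p = 0.53). The hepatocyte transcripts were lower on the PBS arrays by a mean of -2.69 log2 units (exact two-sided p = 0.10), and the complex I call was lost with that index as a covariate (mean -0.15 against -0.22, adjusted p = 0.11).

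The remaining lists moved in both directions or too little to be called. Of the slow fibre genes 5 of 10 rose and 1 fell (median 0.76, adjusted p = 0.065), with Tnni1 at 2.03 ± 0.30, Casq2 at 1.66 ± 0.26 and Tnnt1 at 1.12 ± 0.25, while the slow myosin Myh7 was at 0.66 ± 0.45 (adjusted p = 0.27). Of 13 fast fibre genes only Myh1 rose (0.42 ± 0.15, adjusted p = 0.029; none adjusted over the list alone; list adjusted p = 0.57), its other probe moved the other way, and the fast myosin Myh4 was at -0.06 ± 0.18 (adjusted p = 0.83). In the atrophy list 6 of 13 fell and 2 rose, 7 and 2 adjusted over the list alone (adjusted p = 0.16). The muscle ubiquitin ligases Fbxo32 (-1.34 ± 0.22) and Trim63 (-0.74 ± 0.17) were among those that fell, and the metallothioneins Mt1 (2.35 ± 0.27) and Mt2 (1.49 ± 0.31) were those that rose. In the activin and BMP list 7 of 22 rose and 4 fell (median -0.05, mean 0.12, camera direction up, adjusted p = 0.50). Fstl1 (1.35 ± 0.18), the receptor Tgfbr2 (0.90 ± 0.12) and the activin antagonist follistatin, Fst (0.66 ± 0.18, adjusted p = 0.0069), rose, whereas the activin subunit Inhba (-0.12 ± 0.18) and the receptor Acvr2b (-0.18 ± 0.27) each had an adjusted p of 0.63. Of the circadian genes 6 of 13 fell and none rose, 8 and 1 adjusted over the list alone (adjusted p = 0.13), with Per2 at -1.43 ± 0.49 (adjusted p = 0.025, but 0.071 and 0.056 without PBS replicate 3 or 4). Of 6 adipocyte genes 4 fell and none rose, 5 adjusted over the list alone (adjusted p = 0.065), Lep at -1.29 ± 0.29 among them.

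In the dystrophin complex list 4 of 10 members rose and 1 fell (adjusted p = 0.13): the laminin Lama2 (0.79 ± 0.13), Dtna (0.49 ± 0.10, with 1 of 3 other probes moving the other way) and dystroglycan, Dag1 (0.49 ± 0.12), rose, and the dystrophin homologue Utrn fell (-0.46 ± 0.17, adjusted p = 0.034). Dmd itself, Mstn and Hspa5 were detected on no array by their probes, and Myh2 and Myh3 had no probe named here. At the neuromuscular junction 3 of 8 rose and none fell (adjusted p = 0.13; 1 fell adjusted over the list alone), with Chrnb1 at 1.47 ± 0.12, the esterase Ache at 1.00 ± 0.18 and the clustering factor Agrn at 0.55 ± 0.13. Of the antioxidant genes Gpx1 rose (1.04 ± 0.14) and 6 of 18 fell, Nqo1 (-0.94 ± 0.11) and Gsta4 (-0.94 ± 0.13) most (adjusted p = 0.13), while Hmox1 was at 0.19 ± 0.18 (adjusted p = 0.42). In autophagy 3 of 23 rose and 7 fell (adjusted p = 0.43), the lysosomal protease Ctsb upward by 1.14 ± 0.18 and Lamp2 by 0.70 ± 0.15. Of the heat shock genes 3 of 11 rose and 1 fell (adjusted p = 0.57), Hspb1 by 0.59 ± 0.15. Of 15 endothelial genes 2 fell, none adjusted over the list alone (adjusted p = 0.53), and the vascular growth factor Vegfa was at -0.35 ± 0.13 (adjusted p = 0.040).

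Scaling the arrays to equal medians put the median of all genes at -0.11 in place of -0.05, and 1593 genes were then higher and 2038 lower. The calls of Cox8a (adjusted p = 0.13), Cryab (0.36), Idh3b (0.066), Id2 (0.070), Dnajb1 (0.051), Hspb1 (0.057) and Myh1 (0.37) were lost under that scaling. Ndufb5, Idh3b, Dnajb1, Cryab, Id2 and Per1 also passed, with adjusted p between 0.021 and 0.047. Together with Myh1, Utrn and Vegfa they lost the call without at least 1 single array, and each of the 9 arrays ended the call of at least 1 of them when left out, with adjusted p up to 0.18 (Ndufb5 without wild-type replicate 3).

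**Figure D1:**
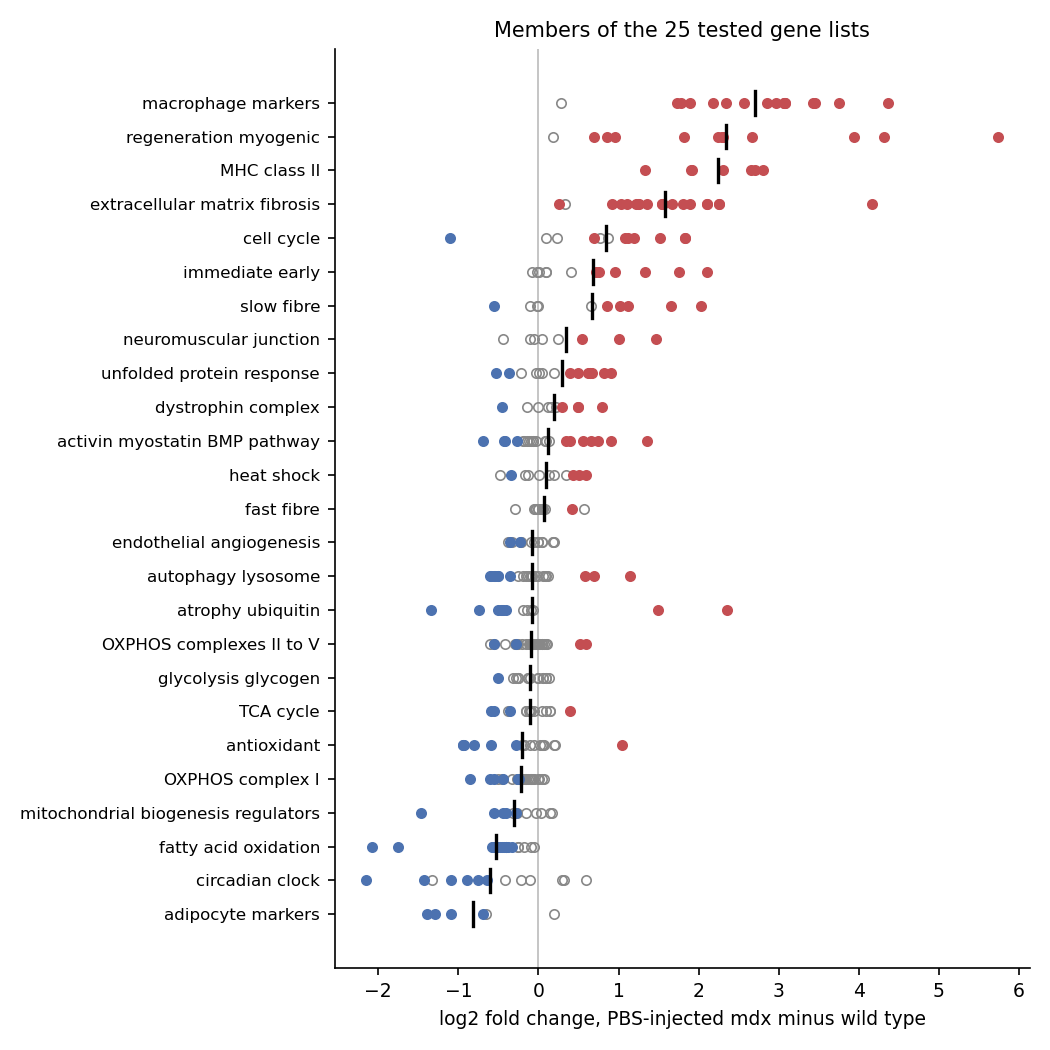
Log2 fold change of each tested member of the 25 lists in PBS-injected mdx (n = 5) against wild type (n = 4); filled points passed the adjusted p limit of 0.05 (red higher, blue lower), open points did not, and black bars are list means. The macrophage, regeneration, MHC class II and matrix lists lie to the right, with medians of 2.96, 2.26, 2.31 and 1.54, and the fatty acid oxidation list lies to the left, with a median of -0.42.

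The next comparison asked what 7 weeks of wheel running changed in PBS-injected mdx muscle (5 arrays against 5). Aqp4, the water channel of fast fibre membranes, rose 1.87-fold, from 6.59 ± 0.19 to 7.50 ± 0.28 log2 units (SD), the level in wild type being 7.79 ± 0.20. Its log2 change was 0.90 ± 0.12 (adjusted p = 0.0011), each of the 5 running arrays (7.14 to 7.89) lay above each PBS array (6.37 to 6.87), and no other gene of 8945 passed. Fatty acid oxidation genes shifted upward as a list: 19 of 22 members had positive values (median 0.20, adjusted p = 4.8e-09), among them the acyl-CoA dehydrogenases Acadvl (0.37 ± 0.12) and Acadm (0.22 ± 0.08) and the isomerase Eci1 (0.29 ± 0.10), though no member passed alone. The call held with an estimated correlation (adjusted p = 0.044). Complex I (29 of 32 members positive, median 0.10, adjusted p = 1.1e-06), complexes II to V (31 of 38, 0.06, adjusted p = 0.00056), the TCA cycle (14 of 16, 0.13, adjusted p = 3e-04) and endothelial genes (14 of 15, 0.21, adjusted p = 0.00023) shifted upward too. Examples were the pyruvate dehydrogenase subunit Pdha1 (0.30 ± 0.11), the complex I subunit Ndufa9 (0.20 ± 0.08) and the endothelial adhesion gene Esam (0.23 ± 0.10). These 4 calls were lost (adjusted p = 0.33, 0.50, 0.22 and 0.33 with an estimated correlation). An exact two-sided permutation test of list means over arrays gave p = 0.024 for fatty acid oxidation and for the TCA cycle. For complex I, complexes II to V and endothelial genes it gave 0.087, 0.13 and 0.12.

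Under running 5 lists shifted downward. In the unfolded protein response 12 of 15 members were negative (median -0.11, adjusted p = 4e-04), with Xbp1 at -0.24 ± 0.09. The 12 cell cycle genes (median -0.26, adjusted p = 0.0014) and the 17 macrophage genes (median -0.19, adjusted p = 0.0033) were all negative, with Mcm2 at -0.31 ± 0.16 and the macrophage receptor Adgre1 at -0.42 ± 0.26. The extracellular matrix (16 of 20 negative, median -0.12, adjusted p = 0.028) and heat shock lists (7 of 11 negative, median -0.07, adjusted p = 0.044) completed the group. These calls were lost (adjusted p = 0.22, 0.62, 0.66, 0.66 and 0.33 with an estimated correlation). In the same order, the exact two-sided permutation test of list means gave p = 0.056, 0.17, 0.29, 0.38 and 0.071. After Aqp4 the lowest p belonged to Tnfsfm13 (0.60, adjusted p = 0.42), then the potassium channel gene Kcng4 (0.82 ± 0.20), the fatty acid transporter Slc27a1 (0.59 ± 0.15), Inip (-0.40), Maml2 (0.47), Adh1 (0.69 ± 0.18) and Selenbp1 (0.32 ± 0.08), each with an adjusted p of 0.89. Myh1 was at 0.50 ± 0.14 (adjusted p = 0.98) and passed when adjusted over the fast fibre list alone. Pdk4 was at 0.43 ± 0.43, Vegfa at -0.21 ± 0.12 and Ppargc1a at -0.17 ± 0.14, none of them past the test. At an unadjusted p under 0.05 there were 297 genes, where chance gives 447. The Aqp4 call was lost with only the compared groups in the model (adjusted p = 0.11). Calls of lists were lost without running replicate 1 (extracellular matrix 0.42, heat shock 0.35), 2 (heat shock 0.052) or 5 (extracellular matrix 0.061, macrophage 0.33), and without PBS replicate 1 (extracellular matrix 0.72, heat shock 0.050), 4 (extracellular matrix 0.068, heat shock 0.15, macrophage 0.097, cell cycle 0.12) or 5 (heat shock 0.12), all adjusted p. Scaling to equal medians ended the extracellular matrix (0.067) and heat shock calls (0.072), no detection filter the former (0.062), and the raw median signal as a covariate (0.050) and the run without the 4 arrays richest in hepatocyte transcripts (0.051) the latter, all adjusted p. The means in these scaling, filter, covariate and 4-array runs were -0.10 to -0.11 for both lists, as in the fit of all arrays. Leaving out single arrays moved some means more. PBS replicate 1 was highest of its group in extracellular matrix genes (10.13, others 9.68 to 9.83). Running replicate 5 was lowest of its group in macrophage genes (9.23, others 9.68 to 10.07). The shifts of these 2 lists became smaller without these arrays. With the hepatocyte index as a covariate complexes II to V (mean 0.04 against 0.08, adjusted p = 0.11), extracellular matrix (-0.09 against -0.11, 0.096) and heat shock (-0.10 in both, 0.086) were not called, while complexes II to V were still called without the 4 arrays (0.08, 0.0011). Over the 9 comparisons, other splits of the same arrays called a median of 4 to 6 lists.

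sActRIIB-Fc was compared with PBS in sedentary mdx to ask what ligand blockade changed (5 arrays against 5). Slow fibre genes shifted upward: all 10 tested members were positive, with a median log2 change of 0.40 (adjusted p = 2.1e-05). The regulatory light chain Myl2 (0.62 ± 0.21) and the tropomyosin Tpm3 (0.79 ± 0.28) rose when adjusted over the list alone, and none did over all genes. Troponin Tnnc1 was at 0.59 ± 0.25, the calcium pump Atp2a2 at 0.42 ± 0.19 and Myh7 at 0.72 ± 0.43. The call was lost (adjusted p = 0.47 with an estimated correlation), and no other list was called. For slow fibre genes the exact two-sided permutation test of list means gave p = 0.016. It gave 0.0079 for autophagy genes, which camera did not call (median 0.07, adjusted p = 0.10). In limma 0 genes passed, 285 had an unadjusted p under 0.05 where chance gives 447, and array weights gave 0 as well. The genes with the lowest p were Drc3 (0.36 ± 0.09, with 1 of 2 other probes moving the other way), Glt28d2 (0.47), the macrophage complement receptor Vsig4 (1.21 ± 0.33, 2.31-fold), Trp53rkb (-0.39), Il4i1 (-0.51 ± 0.15), Mtmr9 (0.36) and Csf3 (-0.38), each with an adjusted p of 1. Fst was at -0.18 ± 0.17, Inhba at -0.22 ± 0.17, Acvr2b at 0.10 ± 0.26, Pdk4 at 0.81 ± 0.43 and Fbxo32 at 0.30 ± 0.21.

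The combination was compared with PBS to ask what both treatments did together (5 arrays against 5). Fatty acid oxidation genes shifted upward, with 19 of 22 members positive (median 0.14, adjusted p = 0.00019), Eci1 at 0.22 ± 0.10 and Acadvl at 0.22 ± 0.12 among them. Complex I shifted the same way (25 of 32 positive, median 0.09, adjusted p = 0.047), and glycolysis genes shifted downward (14 of 16 negative, median -0.15, adjusted p = 0.0034), with Pgm1 at -0.29 ± 0.13 and Pkm at -0.26 ± 0.15. All 3 calls were lost (adjusted p = 0.48, 0.75 and 0.51 with an estimated correlation). In the same order, the exact two-sided permutation test of list means gave p = 0.095, 0.33 and 0.33. In limma 0 genes passed, with 523 at an unadjusted p under 0.05 where chance gives 447, and 8 passed with array weights. Selenbp1 (0.43 ± 0.08), the alcohol dehydrogenase Adh1 (0.88 ± 0.18), the calcineurin regulator Rcan1 (-0.60 ± 0.13), Ret (-0.66 ± 0.15), Fbxl22 (-0.57), the mast cell protease Cpa3 (0.59 ± 0.13), Sult1a1 (0.50 ± 0.11) and Vsig4 (1.42 ± 0.33, 2.68-fold) had the lowest p, each with an adjusted p of 0.23. Vegfa was at -0.36 ± 0.12 (adjusted p = 0.81). Combination replicates 1 and 2 were rich in hepatocyte transcripts (10.65 and 9.90), and without them and the 2 other richest arrays the complex I mean was -0.02 and glycolysis was not called (adjusted p = 0.095). With the hepatocyte index as a covariate complex I was not called (mean 0.04 against 0.07, adjusted p = 0.26). The complex I call was also lost without combination replicate 1 (adjusted p = 0.17), 2 (0.38) or 4 (0.13) or PBS replicate 1 (0.11), 2 (0.11) or 5 (0.086), the glycolysis call without combination replicate 1 (0.074) or 3 (0.068), and 4 genes passed without combination replicate 4. With 1 array left out, the complex I mean ran from 0.031 (without combination replicate 2) to 0.098 (without 3). Combination replicates 1 and 3 were lowest of their group in glycolysis genes (12.32 and 12.30, others 12.62 to 12.88).

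**Figure D2:**
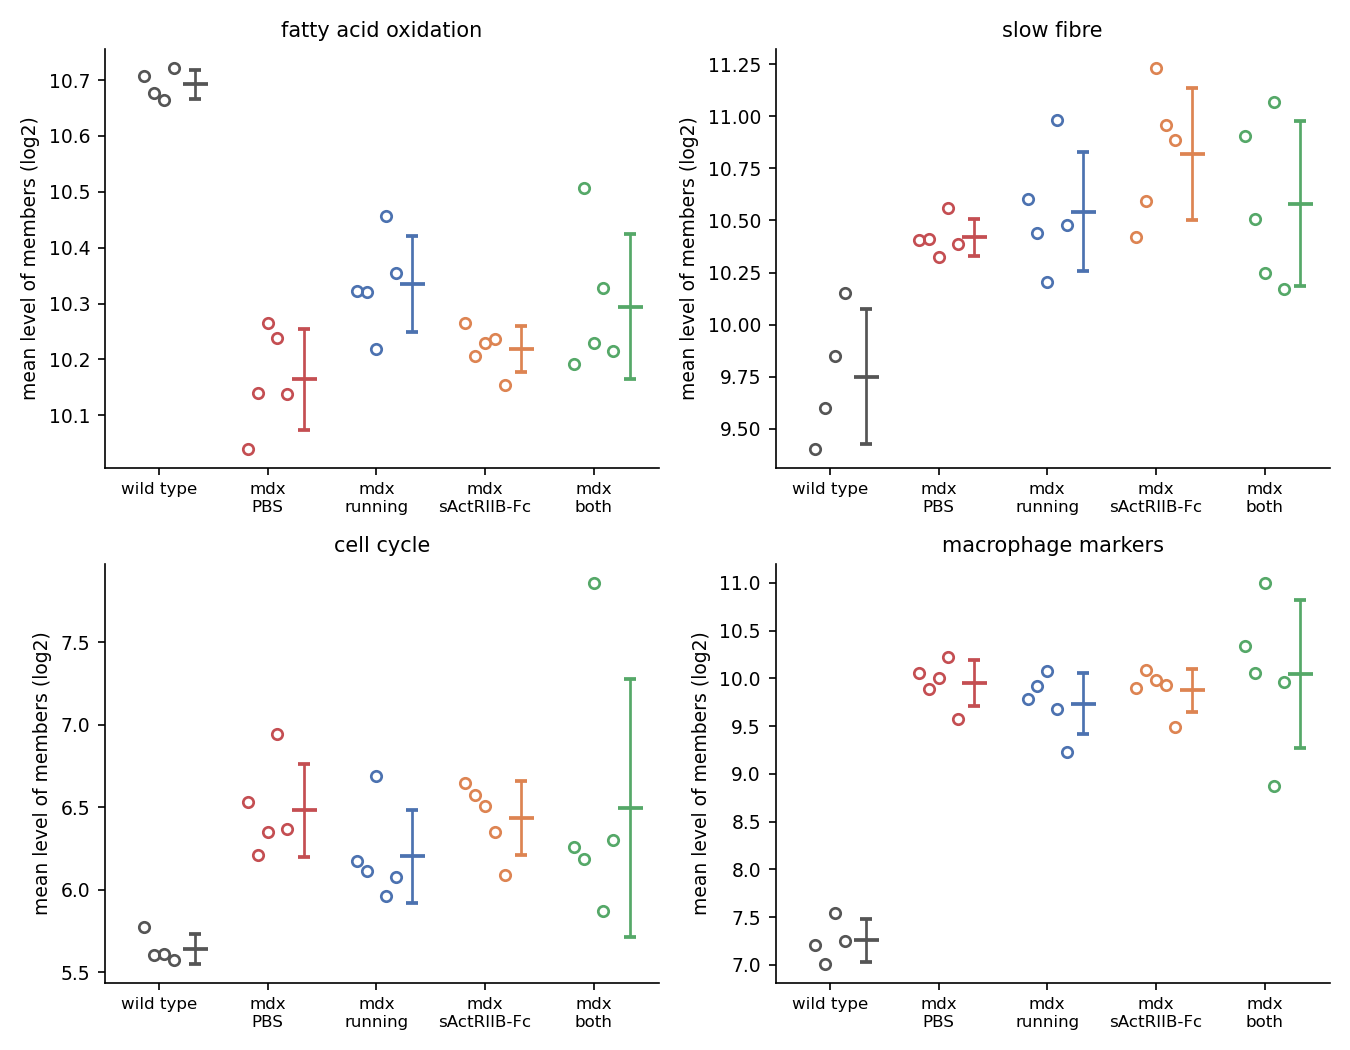
Mean log2 level of the tested members of 4 lists on each array, by group (wild type n = 4, mdx groups n = 5); bars are group means with SD, and the vertical axes do not start at 0. In the cell cycle panel combination replicate 3 stands at 7.86, above the other combination arrays (5.87 to 6.30).

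Adding sActRIIB-Fc to running (combination against running, 5 arrays against 5) shifted macrophage genes upward, with all 17 positive (median 0.32, adjusted p = 5e-04; Cd163 at 0.32 ± 0.19), and cell cycle genes, with 11 of 12 positive (median 0.32, adjusted p = 0.012; Cdk1 at 0.65 ± 0.34). Glycolysis (median -0.16, adjusted p = 0.012), endothelial (-0.15, adjusted p = 0.028), neuromuscular junction (-0.13, adjusted p = 0.045) and TCA cycle genes (-0.09, adjusted p = 0.048) shifted downward, with Phkg1 at -0.39 ± 0.18, Vegfb at -0.28 ± 0.13 and Ache at -0.37 ± 0.17. None of the 6 calls held (adjusted p = 0.72 each with an estimated correlation). The exact two-sided permutation test of list means gave p = 0.42 for macrophage and 0.59 for cell cycle genes. For glycolysis, endothelial, neuromuscular junction and TCA cycle genes it gave 0.32, 0.40, 0.19 and 0.30. In limma 0 genes passed, with 339 at an unadjusted p under 0.05 and 0 with array weights. Slc23a3 (0.69 ± 0.14) and Aqp4 (-0.58 ± 0.12) had an adjusted p of 0.35, Reln (-0.57 ± 0.13) of 0.62, Vsig4 (1.37 ± 0.33) and Popdc2 (-0.37) of 0.66, and Rrad (-1.04 ± 0.26) of 0.82. Fbxo32 was at 0.66 ± 0.21 (adjusted p = 0.90). All 6 list calls were lost without combination replicate 3 (adjusted p = 0.49 for macrophage, neuromuscular junction, endothelial and TCA cycle genes, 0.29 for glycolysis and 0.54 for the cell cycle). Its removal took the macrophage mean from 0.31 to 0.07, glycolysis from -0.15 to -0.08, endothelial genes from -0.13 to -0.07, the neuromuscular junction from -0.15 to -0.09, the TCA cycle from -0.09 to -0.04 and the cell cycle from 0.29 to -0.05. Other single arrays ended calls as well: running replicate 3 (neuromuscular junction 0.050), 4 (TCA cycle 0.18, cell cycle 0.094, endothelial 0.18) and 5 (TCA cycle 0.25, endothelial 0.14, neuromuscular junction 0.16), and combination replicate 1 (glycolysis 0.13, endothelial 0.22, neuromuscular junction 0.10), 4 (TCA cycle 0.098, neuromuscular junction 0.060) and 5 (TCA cycle 0.14, endothelial 0.070). Running replicate 5 was highest of its group in TCA cycle genes (10.95, others 10.65 to 10.84). Combination replicate 1 was low in glycolysis genes (12.32, others 12.30 to 12.88). Both differences became smaller without these arrays. The TCA cycle call was lost with scaling to equal medians (mean -0.07, adjusted p = 0.087) and, at the same mean of -0.09, with the hepatocyte index as a covariate (0.062), and the neuromuscular junction call without a detection filter (0.089). Without the 4 arrays richest in hepatocyte transcripts glycolysis (0.26), endothelial (0.060) and neuromuscular junction genes (0.16) were not called.

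Adding running to sActRIIB-Fc (combination against sActRIIB-Fc, 5 arrays against 5) shifted complex I (27 of 32 positive, median 0.09, adjusted p = 0.00061), complexes II to V (29 of 38 positive, 0.08, adjusted p = 0.0021) and fatty acid oxidation genes (18 of 22 positive, 0.12, adjusted p = 0.0075) upward. Examples were Ndufb2 (0.52 ± 0.19), Cox7a1 (0.33 ± 0.13) and the acyl-CoA dehydrogenase Acads (0.41 ± 0.14). Glycolysis (15 of 16 negative, -0.21, adjusted p = 0.00061) and heat shock genes (9 of 11 negative, -0.21, adjusted p = 0.041) shifted downward, with Phkg1 at -0.51 ± 0.18 and Hspd1 at -0.24 ± 0.09. These calls were lost (adjusted p = 0.68, 0.68, 0.67, 0.58 and 0.58 with an estimated correlation). In the same order, the exact two-sided permutation test of list means gave p = 0.14, 0.21, 0.26, 0.16 and 0.024. In limma 0 genes passed, with 741 at an unadjusted p under 0.05 where chance gives 447, and array weights gave 0. Drc3 (-0.43), Nudt8 (0.49), Amdhd2 (0.49), Acy1 (0.33), Hcfc1r1 (-0.41), Asap2 (-0.30), Selenbp1 (0.32) and Adap2 (0.52) had the lowest p, each with an adjusted p of 0.52. Without combination replicate 2, calls of complex I (adjusted p = 0.093), complexes II to V (0.093), fatty acid oxidation (0.19) and heat shock (0.093) were lost. That array was highest of its group in fatty acid oxidation genes (10.51, others 10.19 to 10.33), so their shift became smaller without it. In heat shock genes it lay among the others (9.48, others 9.43 to 9.59). Without the 4 arrays richest in hepatocyte transcripts, combination replicate 2 among them, all 5 calls were lost: complex I (mean 0.04 against 0.12, adjusted p = 0.79), complexes II to V (0.02 against 0.12, 0.90), fatty acid oxidation (0.04 against 0.08, 0.35), glycolysis (-0.13 against -0.21, 0.076) and heat shock (-0.13 in both, 0.18). With the hepatocyte index as a covariate all 5 were still called (adjusted p = 0.0016 to 0.035), with means of 0.09 for complex I and 0.08 for complexes II to V. Scaling to equal medians ended the glycolysis (0.073) and heat shock calls (0.12). Fatty acid oxidation was also lost without combination replicate 4 (0.069), and heat shock without combination replicate 4 (0.12) or 5 (0.16) or sActRIIB-Fc replicate 4 (0.052) or 5 (0.14).

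Averaged over injections, Aqp4 rose 1.46-fold under running (10 arrays against 10; 0.55 ± 0.09, adjusted p = 0.014). Most of this rise came from the mice without sActRIIB-Fc, already compared above. Running and sedentary means of Aqp4 lay much closer together with sActRIIB-Fc, although the interaction did not pass for this gene. Selenbp1, a selenium-binding protein gene, was next at 0.32 ± 0.06 (adjusted p = 0.069), and passed without combination replicate 3 (0.025). Myh1 (0.45 ± 0.10), which passed adjusted over the fast fibre list alone, the mitochondrial creatine kinase Ckmt2 (0.25 ± 0.06), Asap2 (-0.24), Aldh5a1 (0.41 ± 0.09), Kcng4 (0.60 ± 0.14) and Adh1 (0.54 ± 0.13) had an adjusted p of 0.28. Complex I (30 of 32 positive, median 0.11, adjusted p = 9.7e-09), fatty acid oxidation (18 of 22, 0.14, adjusted p = 9.7e-09), complexes II to V (32 of 38, 0.09, adjusted p = 4.6e-06) and the TCA cycle (14 of 16, 0.04, adjusted p = 0.024) shifted upward. Eci1 (0.29 ± 0.07) and Acadvl (0.29 ± 0.08) rose when adjusted over the list alone. Glycolysis (-0.09, adjusted p = 0.0022), heat shock (-0.16, adjusted p = 0.0041), the unfolded protein response (-0.12, adjusted p = 0.010) and extracellular matrix (-0.11, adjusted p = 0.032) shifted downward, with the chaperone Hspa8 (-0.20 ± 0.06) falling when adjusted over the list alone. None of the 8 calls held (in this order adjusted p = 0.33, 0.058, 0.34, 0.45, 0.34, 0.16, 0.34 and 0.76 with an estimated correlation). The Aqp4 call was lost without the 4 arrays richest in hepatocyte transcripts (log2 change 0.55, adjusted p = 0.20) and with the hepatocyte index as a covariate (0.54, adjusted p = 0.050), while the size of the change stayed the same or nearly so. Scaling to equal medians ended the glycolysis (mean -0.07, adjusted p = 0.14) and extracellular matrix calls (-0.08, 0.14). The extracellular matrix call was also lost without a detection filter (0.058) and with the hepatocyte index (mean -0.08, 0.061) or the raw median signal (-0.10, 0.053) as a covariate, against a mean of -0.10, and the TCA cycle call without the 4 richest arrays (0.06 against 0.07, 0.086). Single arrays ended the call of the TCA cycle (running replicates 4 and 5, combination replicates 2 and 4 and sActRIIB-Fc replicate 4, adjusted p = 0.056 to 0.22), of the unfolded protein response (combination replicate 4, 0.12) and of the extracellular matrix (PBS replicates 1 and 4, running replicates 1 and 5, combination replicates 4 and 5 and sActRIIB-Fc replicate 4, 0.054 to 0.34).

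**Figure D3:**
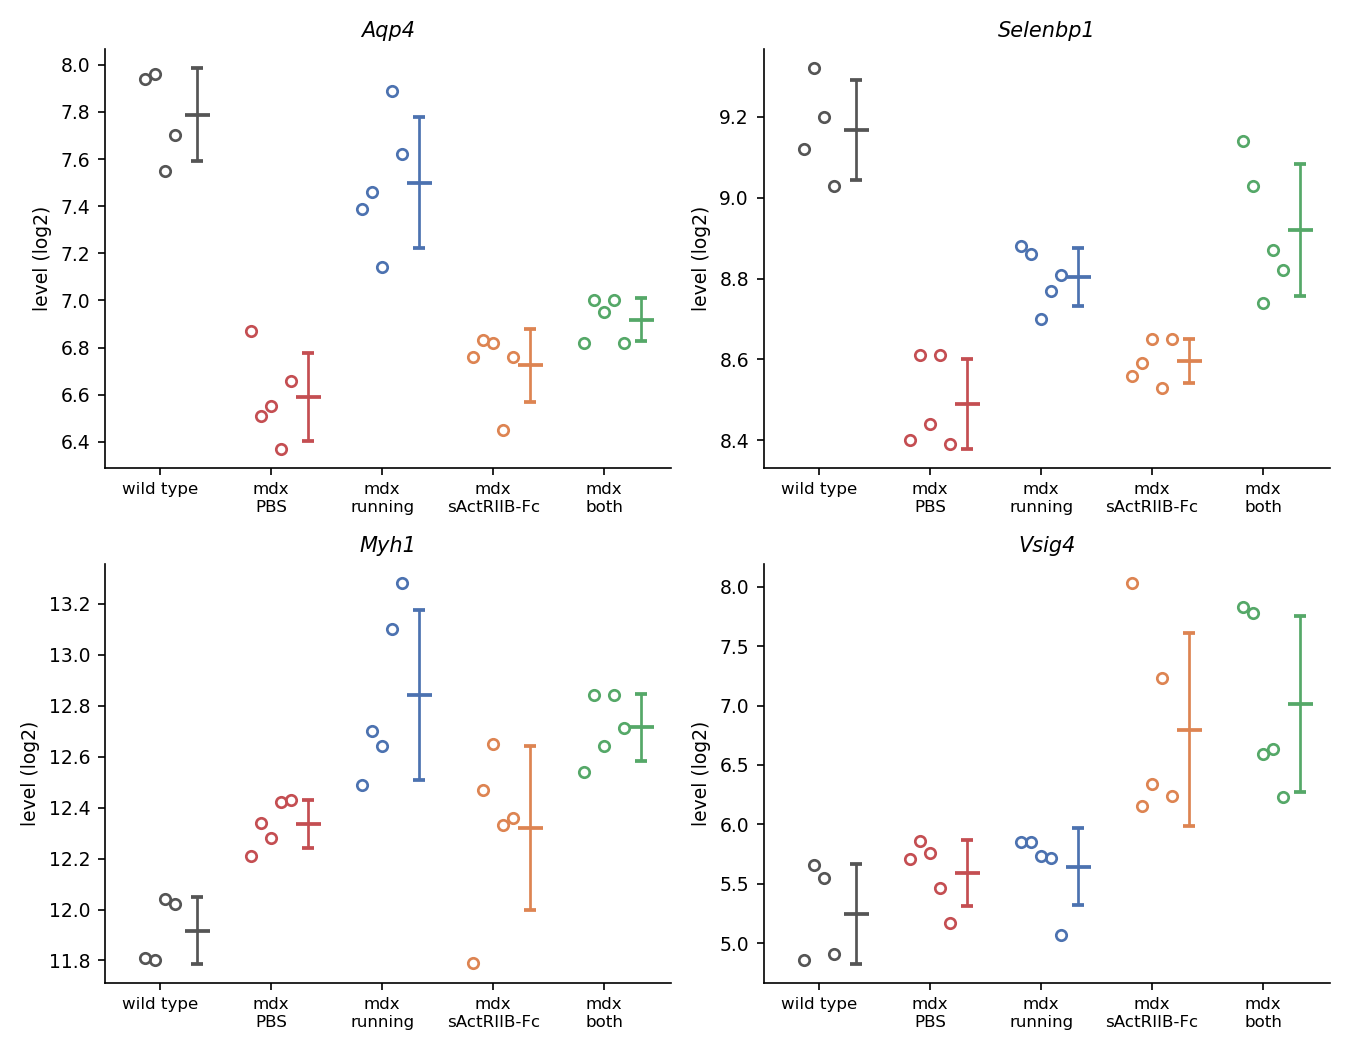
Log2 level of Aqp4, Selenbp1, Myh1 and Vsig4 on each array, by group (wild type n = 4, mdx groups n = 5); bars are group means with SD, and the vertical axes do not start at 0. Aqp4 averaged 7.50 under running, 6.59 under PBS, 6.73 under sActRIIB-Fc and 6.92 in the combination.

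Averaged over activity, sActRIIB-Fc (10 arrays against 10) left Vsig4 at 1.29 ± 0.23, 2.44-fold higher but with an adjusted p of 0.084; Vsig4 passed without combination replicate 5 (0.029) or sActRIIB-Fc replicate 2 (0.049) and with array weights (0.013). Group means of Vsig4 were 5.59 ± 0.28 under PBS, 5.64 ± 0.33 under running, 6.80 ± 0.81 under sActRIIB-Fc and 7.01 ± 0.74 in the combination (SD, n = 5 each). Rcan1 (-0.39 ± 0.09), Slc23a3 (0.42 ± 0.10), Il4i1 (-0.39), Cited4 (-0.43), Glt28d2, Ccndbp1 and Lalba followed, each with an adjusted p of 1. Slow fibre genes shifted upward (9 of 10 positive, median 0.20, adjusted p = 0.0031), as did the atrophy list (10 of 13 positive, 0.09, adjusted p = 0.039), in which Fbxo32 rose when adjusted over the list alone (0.48 ± 0.15). Complex I shifted downward (28 of 32 negative, -0.03, adjusted p = 0.039). None of the 3 calls held (adjusted p = 0.75 each with an estimated correlation). In limma 0 genes passed, with 282 at an unadjusted p under 0.05 and 1 with array weights. The slow fibre call was lost without combination replicate 4 (adjusted p = 0.11). The atrophy and complex I calls were lost with the hepatocyte index (0.10 and 0.13) or the raw median signal (0.11 each) as a covariate, at means of 0.08 and -0.04 in either case, as without them. The atrophy call was lost without any of PBS replicates 1, 3 and 4, running replicates 1, 2 and 4, combination replicates 4 and 5 and sActRIIB-Fc replicates 1 and 5 (0.052 to 0.21), and the complex I call without any of PBS replicates 3 and 4, running replicates 1 and 4, combination replicates 3, 4 and 5 and sActRIIB-Fc replicates 1 and 4 (0.069 to 0.26).

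The interaction asked whether running acted differently with sActRIIB-Fc than without it. The running effect on macrophage genes was higher with sActRIIB-Fc (mean difference 0.39, adjusted p = 0.0039), as was that on cell cycle genes (0.34, adjusted p = 0.036), and it was lower on endothelial (-0.23, adjusted p = 0.0039), glycolysis (-0.21, adjusted p = 0.017) and slow fibre genes (-0.36, adjusted p = 0.017). None of the 5 calls held (adjusted p = 0.66 each with an estimated correlation). In limma 0 genes passed, with 356 at an unadjusted p under 0.05 and 0 with array weights. Drc3 (-0.53), Aqp4 (-0.71 ± 0.17) and Reln (-0.69) had an adjusted p of 0.93. Without combination replicate 3 the macrophage (0.15, adjusted p = 0.36), glycolysis (adjusted p = 0.096), slow fibre (0.076) and cell cycle calls (0.79) were lost. The slow fibre call was also lost without running replicate 1 (0.084) or 4 (0.14), combination replicate 5 (0.20) or sActRIIB-Fc replicate 3 (0.18), the glycolysis call without combination replicate 1 (0.11), and the cell cycle call without PBS replicate 4 (0.17), running replicate 1 (0.10), 2 (0.055) or 4 (0.14) or sActRIIB-Fc replicate 3 (0.064) or 5 (0.12). Scaling to equal medians ended the glycolysis (0.11) and cell cycle calls (0.094). The cell cycle call was also lost without a detection filter (0.10) and, at differences of 0.33, with the hepatocyte index (0.052) or the raw median signal (0.054) as a covariate, and the glycolysis call without the 4 arrays richest in hepatocyte transcripts (0.20).

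A dystrophy score, built from the 1725 genes higher and the 1651 genes lower in PBS-injected mdx, described where treated muscle lay relative to wild type and PBS-injected mdx. Its mean was -1.14 ± 0.05 in wild type, 0.34 ± 0.12 under PBS, 0.21 ± 0.13 under running, 0.29 ± 0.08 under sActRIIB-Fc and 0.30 ± 0.29 in the combination (SD), against a distance of 1.48 between wild type and PBS. Because PBS and wild-type arrays chose these genes, only the other groups were compared. The tests therefore asked what each treatment added to the other. Whether running or sActRIIB-Fc alone moved muscle toward wild type was not tested. The combination differed from sActRIIB-Fc by 0.01 (exact two-sided permutation p = 0.86) and from running by 0.09 (exact two-sided permutation p = 0.55), with 252 splits and 0.0079 as the smallest p they allow. Across 8945 genes, which are not independent replicates, the effect of running without sActRIIB-Fc correlated with that in its presence at r = 0.25 (51.7% of genes with one sign), and the effect of sActRIIB-Fc in sedentary mice with that in runners at r = -0.10 (46.6%). Without combination replicate 3 both the score difference for running (-0.09) and that for sActRIIB-Fc (-0.01) turned negative. The first correlation was 0.045 without running replicate 1 and 0.445 without running replicate 5, and the second reached 0.08 without running replicate 5.

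**Figure D4:**
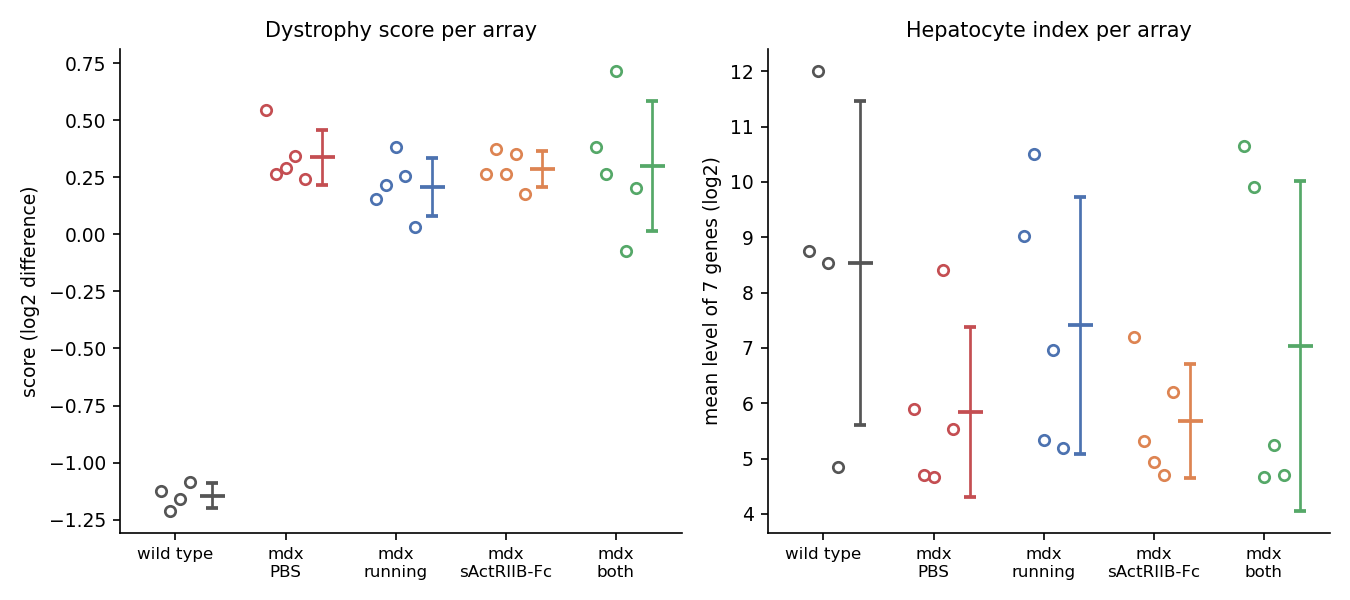
Dystrophy score (left, log2 difference) and mean log2 level of 7 hepatocyte genes (right) on each array, by group (wild type n = 4, mdx groups n = 5); bars are group means with SD. Wild-type and PBS arrays chose the genes of the score, so the distance between these groups is built in. The hepatocyte level spans 4.67 to 12.0 with overlap between all groups.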

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

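Tests chosen only after the result was seen are the splits of running against PBS, that of liver RNA, that of lower hepatocyte transcripts in dystrophic muscle, that of the order of brightness, and the runs with covariates or without the 4 arrays richest in hepatocyte transcripts.

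Combination replicate 3 stood apart in cell cycle genes, with a mean level of 7.86 against 5.87 to 6.30 on the other combination arrays. Wild-type replicate 1 stood apart in the cell cycle (5.77, others 5.58 to 5.61) and immediate early genes (7.30, others 6.89 to 6.92). Running replicate 5 was low in regeneration genes (8.95, others 9.53 to 9.75), high in neuromuscular junction genes (8.21, others 7.95 to 8.01) and low in Vsig4 (5.07, others 5.72 to 5.85), and running replicate 1 was low in heat shock genes (9.34, others 9.54 to 9.61). sActRIIB-Fc replicate 4 was high in extracellular matrix genes (10.09, others 9.78 to 9.83) and Col1a1 (11.01, others 10.18 to 10.41) and low in Aqp4 (6.45, others 6.76 to 6.83). sActRIIB-Fc replicate 3 was low in dystrophin complex genes (8.71, others 8.82 to 8.87), and replicate 5 was high in endothelial genes (9.01, others 8.79 to 8.85) and had fewer detected probes (11088, others 11491 to 11539). Wild-type replicate 4 was high in glycolysis (13.01, others 12.79 to 12.82), endothelial genes (9.01, others 8.78 to 8.82) and Lama2 (7.61, others 7.37 to 7.41) and low in Cox6a1 (10.11, others 10.37 to 10.42) and Pdia3 (8.73, others 9.09 to 9.13), and wild-type replicate 3 was low in mitochondrial biogenesis genes (8.92, others 8.98 to 8.99).

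PBS replicate 5 was low in Ccl8 (9.04, others 9.76 to 10.05), Gpnmb (11.15, others 11.87 to 12.13), Ces1d (7.97, others 8.98 to 9.39), Cox8a (11.28, others 11.50 to 11.57) and Idh3b (8.72, others 9.11 to 9.17). PBS replicate 4 was low in Timp1 (10.21, others 10.32 to 10.34) and high in TCA cycle genes (10.70, others 10.61 to 10.63) and in the hepatocyte gene Gnmt (7.12, others 5.00 to 5.34), and PBS replicate 1 was high in Cpa3 (7.41, others 7.08 to 7.16). Combination replicate 1 was low in Kcng4 (6.43, others 7.26 to 7.47), and combination replicate 4 was high in Bcl6 (10.84, others 10.13 to 10.24) and Acy1 (7.71, others 7.48 to 7.54). These 31 values came from 489 groups of arrays, of which chance sets apart about 1 in 20. Of them 5 each fell on wild-type replicate 4 and PBS replicate 5.

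In the test of the interaction, camera called differences of the running effect with sActRIIB-Fc in macrophage (0.39), cell cycle (0.34), glycolysis (-0.21), endothelial (-0.23) and slow fibre genes (-0.36), and none of these calls held (adjusted p = 0.66 each with an estimated correlation). Without combination replicate 3 the calls of macrophage (0.147, adjusted p = 0.36), cell cycle (-0.002, 0.79), glycolysis (-0.136, 0.096) and slow fibre genes (-0.279, 0.076) were lost.

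Hepatocyte transcripts differed between arrays of one group by far more than muscle genes. A list of 30 further hepatocyte genes was tested against the mean of the first 7, and each of the 23 tested genes followed it across the 24 arrays (r above 0.5, median 0.93), although Cyp2e1, Trf, Mup2, Mup6 and Gsta3 were detected on all 24 arrays and Alb, Fabp1, Fgb, Tdo2 and Tat, some of them abundant in liver, on none. Of 60 ribosomal protein genes 5 (8.33%) were also detected on no array, so a silent probe alone excludes little. Genes that failed the detection filter were left out, and some passed it on few arrays, as Cyp3a11 and Hpd on 4 each. For such genes the filter favoured a high r. Cyp2e1, Trf, Mup2, Mup6 and Gsta3, detected on all 24 arrays, had r of 0.54, 0.70, 0.94, 0.93 and 0.92. Lower hepatocyte transcripts in dystrophic muscle are argued against as the whole cause, since the lowest wild-type array (4.85) lay below the highest PBS array (8.41). This overlap rests on 1 array of each group. The other wild-type arrays lay at 8.54 or more and the other PBS arrays at 5.89 or less. Liver RNA carried into some samples may explain the pattern, while pancreas or kidney RNA stays open, because only 3 of 12 of their genes could be tested (median r 0.26). Those 3 were the pancreas genes Cela1, Cela3b and Amy2a5. The kidney genes Umod, Slc34a1, Kap and Slc22a6 were detected on no array.

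The raw median signal was highest on the array numbered 1 in 5 of 5 groups (chance 4e-04), and the mean rank correlation of number and signal within groups was -0.98. Chance is excluded as the cause of this order by a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. The position of the arrays on a slide is a candidate explanation that could not be tested, since no slide is named, and the design gives no biological explanation to test.

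The list shifts under running in PBS-injected mdx were tested against both of these patterns. With the raw median signal as a covariate 9 of the 10 lists were still called. That signal spanned 81.11 to 95.91 on the running arrays and 79.1 to 98.98 on the PBS arrays. A covariate so alike in both groups could remove little of their difference, so this count does not decide on brightness. With the hepatocyte index 7 of 10 were still called. Other splits of the same arrays called a median of 5 lists, and 1 of the 10 calls held with an estimated correlation. Remaining called is therefore weak evidence, and this count does not decide on RNA from liver either. Extracellular matrix (adjusted p = 0.096), complexes II to V (0.11) and heat shock (0.086) lost the call with the hepatocyte index, and their means were -0.09, 0.04 and -0.10 against -0.11, 0.08 and -0.10 without it. Chance is not excluded for the number of lists, as 10 of 100 splits of the same arrays gave as many. Metabolic adaptation to running remains open as a biological explanation, consistent with the fatty acid oxidation shift, and was not separated from the structure among the arrays.

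Splits of the arrays excluded chance for the genes changed between mdx and wild type (1 of 100 splits gave as many, the real 3376 against at most 2389 in another, which moved PBS replicate 5 to the wild-type side). For the single gene called under running the share was under 0.05 as well, against PBS (3 of 100, 1 against 1) and averaged over injections (3 of 100, 1 against 5), but other splits reached as many or more, and a count of 1 gives little ground to exclude chance. For the other comparisons the real count was 0, which 100 of 100 splits reach, and other splits gave up to 0 genes for sActRIIB-Fc against PBS, 1518 for the combination against PBS, 1306 for sActRIIB-Fc in runners, 6 for running under sActRIIB-Fc, 570 for sActRIIB-Fc averaged over activity and 2 for the interaction. The largest of these, combination replicates 4 and 5 with PBS replicates 2, 3 and 5 against the rest, and running replicates 2, 4 and 5 with combination replicates 4 and 5 against the rest, point to a structure of the samples other than the groups. In both, combination arrays 4 and 5 stand against 1 to 3, and the mean hepatocyte index was 4.97 against 7.90 and 6.53 against 7.92 on the sides. Single arrays did not follow these means. Combination replicate 3 (4.67) stood on the side of the higher mean in both splits, and running replicate 2 (10.51) on that of the lower mean in the second. The raw median signal was lower on combination replicates 4 and 5 (77.31 and 75.96) than on 1 to 3 (98.39, 89.24 and 89.06). Not every array followed this order. PBS replicate 2 (91.04) stood with combination replicates 4 and 5, and PBS replicate 4 (84.75) against them. Running replicate 2 (90.75) stood with them, and running replicate 3 (86.4) against them. What made these splits, whether liver RNA, the order of brightness or another difference between the samples, was not tested. Chance was not excluded for any number of lists: 26 of 100 splits reached it for mdx against wild type (9 lists, at most 13), 95 for sActRIIB-Fc (1, 8), 92 for the combination (3, 14), 54 for sActRIIB-Fc in runners (6, 11), 58 for running under sActRIIB-Fc (5, 12), 25 for running averaged (8, 12), 77 for sActRIIB-Fc averaged (3, 13), 63 for the interaction (5, 16), and the highest other count for running against PBS was 13 beside the real 10. It was not excluded either for the correlation of the running effects (0.249, 26 of 100, at most 0.564) or of the sActRIIB-Fc effects (-0.097, 72 of 100, at most 0.574). A count of lists does not measure how far the lists moved. In the exact two-sided permutation test of list means, each of the 9 lists called in mdx against wild type gave p = 0.0079, the smallest possible. Some lists that were not called, such as slow fibre genes, gave the same value.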

How the results depend on the processing

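The runs with the hepatocyte index or the raw median signal as a covariate, and without the 4 arrays richest in hepatocyte transcripts, were chosen after seeing the data. With all settings that leave no single array out, named genes kept their side of the limit in 3337 runs, lost the call in 41, gained it in 16 and turned in 0; lists kept the call in 369, lost it in 130 and turned in 1. Leaving out single arrays, genes kept their side in 3133 runs, lost the call in 53 and gained it in 6, and lists kept it in 552, lost it in 97 and turned in 2. Except where a setting tests fewer arrays, the cause was not tested.

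Genes changed by running averaged over injections numbered 2 without background correction, with the authors' values, without a detection filter and with array weights, 3 with the raw median signal and 0 without the 4 arrays. The combination gave 8 and sActRIIB-Fc averaged over activity gave 1 with array weights; sActRIIB-Fc averaged also gave 1 with the hepatocyte index, the raw median signal or the replicate number as a block. Running against PBS gave 0 with only the compared groups. With that block mdx against wild type gave 3739 genes. It ended the calls of complex I in the combination (adjusted p = 0.055), heat shock under running (0.058) and Ndufb5 in mdx (0.051), and Vsig4 passed with it for sActRIIB-Fc averaged (0.017). Of 46 pairs of one number 25 correlated above 0.1 (-0.44 to 0.65), with a mean of 0.14 against -0.04 for other pairs; the number also orders the raw signal (mean rank correlation -0.98), so these values do not settle a pairing. A slide block was not run.

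Lists for sActRIIB-Fc averaged numbered 5 without background correction, with the authors' values and without a filter, 1 with the hepatocyte index and 9 without the 4 arrays. Median scaling gave 16 for mdx against wild type, 6 for sActRIIB-Fc against PBS, 3 for running under sActRIIB-Fc and 3 for the interaction. No filter gave 5 for the combination, and leaving out the 4 arrays gave 1 for running under sActRIIB-Fc and 8 for the interaction. An estimated correlation gave 3 for mdx against wild type, 1 for running against PBS and 0 for the other 7 comparisons; fry gave 19, 1, 1 for running averaged and 0 for the rest. The score difference for running was -0.0449 with genes changed at least 2-fold, -1e-04 with median scaling, -0.0664 with the raw median signal and -0.0059 without the 4 arrays. Complex I in the combination was -0.019 without the 4 arrays. Without single arrays the cell cycle ran from -0.05 to 0.448 for sActRIIB-Fc in runners and from -0.002 to 0.496 for the interaction, lowest without combination replicate 3 and highest without 4.

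Leaving out single arrays gave 2903 to 3277 genes for mdx against wild type, 1 to 1 for running against PBS, 0 to 4 for the combination, 1 to 2 for running averaged and 0 to 1 for sActRIIB-Fc averaged, and 0 to 0 for the rest. Lists numbered 9 to 11 for mdx against wild type, 6 to 12 for running, 1 to 5 for sActRIIB-Fc, 1 to 10 for the combination, 1 to 9 for sActRIIB-Fc in runners, 1 to 9 for running under sActRIIB-Fc, 5 to 12 for running averaged, 1 to 7 for sActRIIB-Fc averaged and 2 to 7 for the interaction. Score differences ran from -0.0914 to 0.1112 for running and -0.0136 to 0.1887 for sActRIIB-Fc, and the correlations of effects from 0.045 to 0.445 and from -0.238 to 0.084. Genes near background are limited by the signal over the control beads.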

Other observations

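The test on genes of denervated muscle was chosen only after the result was seen.

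Igf2, the fetal insulin-like growth factor and an imprinted gene, rose by 3.57 ± 0.21 in PBS-injected mdx against wild type (n = 5 and 4, adjusted p = 7e-12), from 9.81 ± 0.12 to 13.38 ± 0.34 log2 units (SD). Other genes on a list of imprinted growth genes rose with it. Among them were Mest by 2.75 ± 0.30, the growth factor adaptor Grb10 by 1.27 ± 0.14 and the cell cycle inhibitor Cdkn1c by 1.11 ± 0.13. Peg3 rose by 1.17 ± 0.23, the receptor Igf2r by 0.75 ± 0.15 and Cd81 by 0.71 ± 0.08. The rise of Igf2 prompted that list. Of its 21 genes, 13 besides Igf2 were tested, of which 8 rose and 0 fell (median 0.48). One of the 8, Dcn (0.26 ± 0.09), was also on a list fixed in advance. Over all 8945 genes 1725 rose and 1651 fell. The hypothesis that this network is higher in dystrophic muscle was tested with Igf2 left out. The unadjusted camera p was 0.00012 (0.0051 with an estimated correlation) and the median was above 0, as the hypothesis predicted. Since regenerating fibres express many of these genes, regeneration may account for the shift, and the test does not separate these explanations.

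Some genes known to rise when muscle loses its nerve supply were higher as well, on a list written after the rise of Sln (4.73 ± 0.26) had been seen: the neuropeptide gene Gal by 3.51 ± 0.72, the stress ankyrin Ankrd1 by 3.04 ± 0.16 and Gadd45a by 0.93 ± 0.13, while the deacetylase Hdac4 was at -0.30 ± 0.17. Others went the other way, as the ubiquitin ligases Fbxo32 (-1.34 ± 0.22) and Trim63 (-0.74 ± 0.17), which denervation is known to induce and which the list did not hold, fell. A first camera run kept Sln in the set (p = 5.7e-05); with Sln left out, and also Chrna1, Chrng, Ncam1, Runx1 and Myog, which were on the lists fixed in advance and all rose (0.86 to 4.31), 3 of 4 rose (median 1.99, p = 0.0026, 0.0065 with an estimated correlation). That set lies below the limit of 5 tested members held for all other lists, so its p does not decide on the hypothesis of a denervation-like program. New fibres also express these genes before they are innervated, and the sources could not be told apart.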
